A study of Mus musculus with 8 samples.

How the data were processed

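Total RNA of mouse keratinocytes of the C57Bl6 strain was labelled with biotin and hybridised to Illumina arrays, per the labels' protocols. The 8 arrays were 4 of type I keratin KO cells and 4 of wild-type cells, numbered 1, 2, 3 and 1.1 in each genotype. The deposited table holds 1 intensity per probe and array on a linear scale for 25697 probes. How the authors made these intensities is not given in the sources used here. The values show that they were background-subtracted, because 27.1% to 27.3% of probes per array were negative, with a minimum of -12.8. All 8 arrays shared the same minimum, 75th percentile (98.8) and maximum (20141), as quantile normalization leaves them, and their medians lay between 8.04 and 8.12. A further table of non-normalized signals and detection p-values was not used here, because the names of its 16 value columns matched no sample label.

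The design fixed before the data were examined assumed non-normalized signals and the neqc procedure, and log2 of the values where they proved normalized already, which applied. An offset of 16 was added before log2, since negative values have no log. Fold changes are therefore on the log2(intensity + 16) scale and understate the change of dim genes. A background limit was set from the negative values, taken as noise and mirrored around 0, so that 5% of the mirrored noise lay above it. The limit was an intensity of 6.30, and each array had 53.0% to 53.2% of its probes above it. A probe was kept if it exceeded the limit on at least 3 arrays, as 14453 did. For a gene not above the limit on any array of a genotype, the fold was given as a bound, with the mean log2 of the bright group set against the limit. The number of arrays limits the precision of every value.

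Probe names came from the platform annotation, which may be old. Of the probes, 23978 had 1 gene symbol, 0 had several and 1719 had none. Gene IDs of 23962 probes were found in the mouse gene table of assembly GRCm38.p6, which changed 0 symbols. The array files name no genome build, so no coordinates are given. Of several bright probes for a gene, the 1 with the highest mean was tested, which gave 9881 genes, and 889 bright probes without a symbol were left out.

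Before any fit the arrays were compared by the SD of their log2 differences over bright probes. The close pairs, wild-type 1 with 1.1 and KO 3 with 1.1, had correlations of 0.995 and were averaged on the log2 scale. The labels name KO 1.1 as a repeat of KO 1, and the fixed design averaged those arrays. The pairing by agreement replaced it after the arrays were seen, and the numbers of genes under both pairings and without the 1.1 arrays were seen together. Genes were compared with limma's lmFit and eBayes, 3 KO against 3 wild-type replicates with no block. Benjamini-Hochberg adjustment covered all genes tested, and a gene was called at an adjusted p under 0.05. All adjusted p values for single genes are from limma.

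Of 40 gene lists fixed in advance, those with at least 5 tested members entered camera with a preset correlation of 0.01, adjusted over the 32 lists, and the list of sex genes was not tested as a list. Camera with an estimated correlation, camera on ranks and fry were alternatives. Camera on ranks and the list tests under all other settings kept the preset correlation. The named genes followed a fixed rule. It took Tslp, every measured type I keratin, Krt18 and 6 type II keratins, and the sex genes Xist, Ddx3y and Eif2s3y. It also took the 12 largest rises and the 12 largest falls among called genes with no overlap of replicates, leaving out type I keratins and sex genes. For each list it took all called members where 5 or fewer were called, and otherwise the 4 with the largest change, or the 2 with the largest change where none was called. Genes named outside it are said to be chosen after their values were seen.

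The fit was tested on simulated data with the spread of these 9881 genes. It called 47.2%, 91.9% and 97.4% of genes changed by 1, 2 and 3 on the log2 scale, with 5.12% false among its calls. A list shifted by 0.5 was called in 10 of 10 simulations, and 1 of 310 unshifted lists was called. Each simulated gene's spread was drawn from the fitted prior, whatever its intensity, and was equal in all replicates. The rates therefore do not cover a replicate that stands apart from the others. The simulated genes were drawn independently of each other, so these rates do not cover genes that move together. In the data the correlation estimated within a list reached 0.84, for the melanocyte markers. Alternatives covered the pairing of arrays, blocks, offset, filters, probe choice, prior, array weights, thresholds, centring, sex and each replicate left out. R 4.3.3, limma 3.58.1 and statmod 1.5.0 were used, with figures drawn in matplotlib 3.10.9.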

Results

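Transcript levels were measured in cultured mouse keratinocytes on 8 Illumina expression arrays, 4 from cells lacking the type I keratin genes (KO) and 4 from wild-type cells. Type I keratins are the acidic keratins, which pair with basic type II keratins to build the intermediate filaments of epithelial cells. The cells came from the skin of E18.5 embryos, shortly before birth, and were grown to confluency. Each genotype had replicates 1, 2 and 3 plus an array numbered 1.1, which the labels describe as a repeat of replicate 1. The arrays of wild-type replicates 1 and 1.1 differed with an SD of 0.205 on the log2 scale. KO array 1.1 lay equally close to KO replicate 3 (SD 0.213) and far from KO replicate 1 (SD 0.640), while the other pairs within a genotype differed with an SD of 0.418 to 0.640. Each close pair was therefore averaged and counted as 1 sample, which left 3 KO and 3 wild-type replicates. Nothing in the labels says that the replicates came from separate embryos, so p-values measure only the spread between these samples. This spread was not purely technical, because the sex-linked gene Eif2s3y read -2.27 in KO replicate 1 and 1248 in KO replicate 2, and -0.18 in wild-type replicate 3 and 1186 in wild-type replicate 2.

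The first comparison asked whether the deleted genes were silent in the KO cells. Krt17, Krt16 and Krt10 were not above background on any KO array and were bright on all 4 wild-type arrays. Krt17, a keratin of stressed and appendage epithelium, fell at least 2858-fold, from an intensity of 18013 ± 260 (SD, n = 3). Krt16, its wound-response relative, fell at least 1632-fold from 10453 ± 2232 (SD, n = 3), and Krt10, the keratin of suprabasal cells, fell at least 80.8-fold from 561 ± 317 (SD, n = 3). Krt14, the partner of Krt5 in basal cells, fell from 18483 ± 647 to 4.32 ± 5.31 (SD, n = 3 each), and 1 of the 4 KO arrays stayed above background. Krt42 fell from 86.5 ± 32.0 to 2.58 ± 2.07 (SD, n = 3 each), with 1 of the 4 KO arrays above background, so its mean KO level lay below the background limit of 6.30. The bounds for Krt17, Krt16 and Krt10 set the wild-type mean against the background limit. Krt14 and Krt17 both held the values 17835.6 and 19130.6 on wild-type arrays, since quantile normalization gives the brightest probes shared values. Their wild-type SDs therefore partly reflect steps between such values and may not measure the spread between samples. For the 5 genes limma's adjusted p values ran from 3.56e-07 for Krt17 to 0.0128 for Krt42.

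Of the 22 type I keratins of the fixed list with a probe, 8 were not above background on any array and 9 were bright enough to test. Of those 9, 5 fell when adjusted over all genes, and 6 passed when adjusted over the list alone. The sixth was Krt23, which was above background on all 4 wild-type arrays and no KO array, at least 9.31-fold lower with an adjusted p of 0.108 over all genes. Krt15 differed by -0.41 and Krt33a by 0.22 on the log2 scale. Krt15 was above background on 2 of the 4 KO arrays and Krt33a on all 4, and both on all 4 wild-type arrays. On the KO arrays Krt15 read 3.83 to 12.4 and Krt33a 8.17 to 18.6, and on the wild-type arrays Krt33a read 9.85 to 14.3. The limit lets 5% of the mirrored noise pass, and Krt24, Krt27 and Krt31 each exceeded it on 1 KO array, at 6.71, 8.78 and 9.11. The KO cells lack the type I keratin genes, so these readings are no evidence that Krt15 and Krt33a were expressed there. The source of the signal of these 2 probes on the KO arrays was not tested. Krt20 was above background on 3 of the 4 wild-type arrays and no KO array, too dim for a fold, and none of these 3 passed. The list as a whole shifted lower in camera, a test of a gene list against all other genes (adjusted p = 7.1e-13), and did not pass with an adjusted p = 0.271 with an estimated correlation. The series chose this list by deleting its genes, so its direction is not independent evidence.

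None of the 7 other keratins named in advance passed the test. Krt5, the basal type II keratin, stood at 8667 ± 1411 in KO and 9008 ± 939 in wild type (SD, n = 3 each), a log2 difference of -0.06 ± 0.18 (SE). Krt6b differed by 0.02 ± 0.18 and Krt6a by -0.66 ± 0.35. Krt18, a type I keratin of simple epithelia whose gene lies apart from the others, was measured 2.08 ± 0.62 higher (adjusted p = 0.150). Krt7, a simple-epithelial type II keratin, was measured 2.35 ± 0.75 higher (adjusted p = 0.171), and Krt8 0.45 ± 0.96 and Krt1 -0.39 ± 0.14. Krt7 read 138, 316 and 1546 in KO replicates 1, 2 and 3, and its log2 difference ran from 1.42 to 3.09 over its alternatives. In the type II keratin list, 0 of 13 members passed limma's test, 2 had an unadjusted p under 0.05 (Krt7 and Krt1), and the list did not shift (adjusted p = 0.843). Of all genes tested, 17.1% had an unadjusted p under 0.05, the share beside which such counts of list members should be read. The list's mean and median were 0.17 and 0.02 while camera's direction was down.

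**Figure D1:**
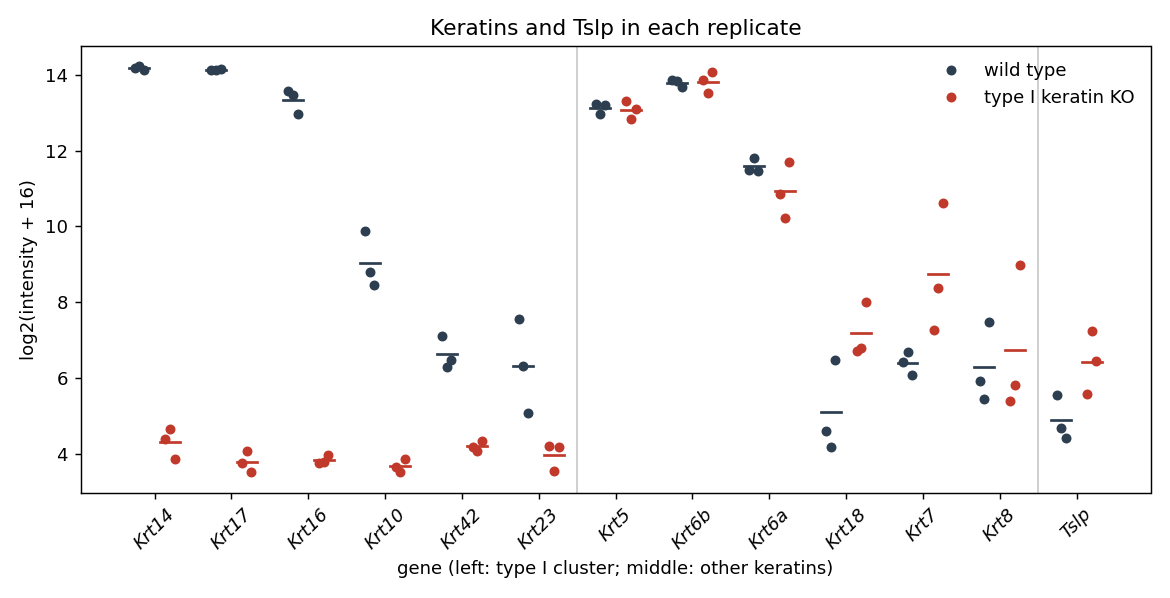
Each point is a replicate's log2(intensity + 16) for the gene named on the horizontal axis, in wild-type (dark) and KO (red) cells, with 3 replicates each and a line at the group mean. Krt14 and Krt17 means lay at 14.17 and 14.14 in wild type and at 4.31 and 3.79 in KO, whereas Krt5 lay at 13.13 and 13.07.

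The second comparison concerned Tslp, the epithelial cytokine of allergic inflammation that the series is about. Its probe read 79.7 ± 51.6 in KO and 15.6 ± 13.9 in wild type (SD, n = 3 each), and every KO replicate lay above every wild-type replicate. The margin was narrow, with KO replicate 1 at 31.9 and wild-type replicate 1 at 31.4, and 1 of the latter's arrays, at 34.0, read above KO replicate 1. The log2 difference was 1.53 ± 0.45 (SE), or 2.89-fold on the scale with the offset of 16, and it did not pass over all genes (limma adjusted p = 0.149). Adjusted over the list alone, among 13 alarmins and type 2 cytokine genes, the adjusted p was 0.0472, which is not independent evidence because the series named the gene. An exact two-sided permutation test of the 6 replicates gave p = 0.1, the smallest value that 3 against 3 can give, and rests on that margin. The second Tslp probe was not above background on any of the 8 arrays.

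Other genes of the alarmin and type 2 cytokine list moved in both directions. S100a7a, an S100 protein of inflamed skin, rose by 3.40 ± 0.34 (SE) on the log2 scale, from 71.1 ± 25.0 to 925 ± 358 (SD, n = 3 each; adjusted p = 0.0132). Il13ra1, a receptor chain for interleukin 13, fell by 2.07 ± 0.26, from 429 ± 102 to 90.5 ± 26.9 (adjusted p = 0.0264). Of the list's 13 tested members, 1 rose, 1 fell and 11 did not pass over all genes, and 3 passed when adjusted over the list alone. The list did not shift (adjusted p = 0.326; 3 members positive and 10 negative), but passed as lower without KO replicate 3 (0.0253; 0.0253 to 0.926 over its alternatives).

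The third comparison covered all genes. Of 9881 genes tested, 70 changed, 29 higher and 41 lower in KO, and 65 remained without the type I keratins, 36 of them lower. The gene with the greatest rise was Ppbp, the precursor of a neutrophil-attracting chemokine, which rose by 6.84 ± 0.63 (SE) on the log2 scale, from 27.1 ± 25.0 to 5577 ± 4232 (SD, n = 3 each; adjusted p = 0.0125). Abcc3, an efflux transporter, rose by 2.58 ± 0.41 and Zfhx3, a transcription factor, by 2.47 ± 0.20. Abcc3 was above background on only 2 of the 4 wild-type arrays, and its log2 difference ran from 1.69 to 3.48 over its alternatives. Plaur, the urokinase receptor, rose by 2.32 ± 0.37, Dusp4, a MAP kinase phosphatase, by 2.25 ± 0.20, and Edn2, an endothelin, by 2.19 ± 0.28. Gprc5a rose by 2.11 ± 0.24, Upp1, uridine phosphorylase, by 2.04 ± 0.29, and Gadd45g, a growth arrest gene, by 1.91 ± 0.25. Upp1 too was above background on only 2 of the 4 wild-type arrays, and its log2 difference ran from 1.23 to 3.14 over its alternatives. The guidance factor Sema3c rose by 1.83 ± 0.18 and the esterase Esd by 1.80 ± 0.23.

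Among the genes that fell outside the type I keratins, Stfa2 and Cstdc6, cysteine protease inhibitors of the stefin A family, fell by 3.06 ± 0.44 (SE) and 2.22 ± 0.33 on the log2 scale. In KO cells Cstdc6 was above background on 2 of 4 arrays, with a mean of 6.24 against the limit of 6.30. These family members have near-identical sequences, so which copy was measured is uncertain. Palmd fell by 2.62 ± 0.33, Rgma, a co-receptor of bone morphogenetic proteins, by 2.47 ± 0.31, and Vegfd, a lymphatic growth factor, by 2.23 ± 0.24. Tnfrsf18, a tumour necrosis factor receptor family member, fell by 2.22 ± 0.25, Mtmr11 by 2.19 ± 0.34, and Pou3f1, a transcription factor of keratinocytes, by 1.94 ± 0.24. The transcript 2310034C09Rik was not above background on any KO array and fell at least 5.28-fold (adjusted p = 0.0177). The p53 target Trp53inp1 fell by 1.81 ± 0.29 and the transcription factor Sox21 fell by 1.81 ± 0.28. Sesn1, another p53 target, fell by 1.26 ± 0.18. Dsc3, a desmosomal cadherin, fell by 1.53 ± 0.24, from 1446 ± 271 to 497 ± 141 (SD, n = 3 each). Socs3, an inhibitor of cytokine signalling chosen after its values were seen, fell by 1.55 ± 0.18.

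**Figure D2:**
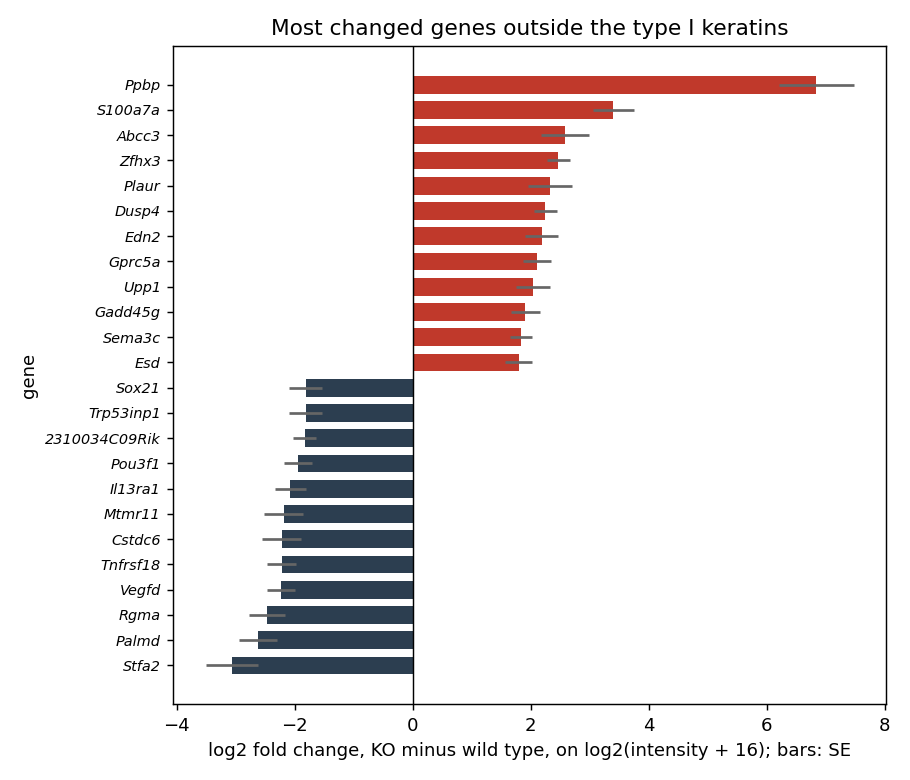
Bars give the log2 fold change (KO minus wild type, on log2(intensity + 16)) of the 12 genes with the largest rise and the 12 with the largest fall among genes that passed the test, outside the type I keratins, with 3 replicates per genotype and SE as error bars. They run from 6.84 for Ppbp to -3.06 for Stfa2, and the bar of 2310034C09Rik, not above background on any KO array, is a fitted value.

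In all 70 changed genes the KO replicates lay on 1 side of the wild-type replicates. A call at this threshold nearly requires that, so it is no further evidence for these genes. Of all genes tested 22.5% showed such a separation, against 10% by chance. Of the changed genes, 24 had several bright probes, and in 22 of these every probe pointed the same way. Averaging the arrays as the labels number them, the fit planned before the data were examined, gave 261 genes, and leaving out both 1.1 arrays gave 57. Averaging KO 1.1 with KO 3 replaced the planned fit after the agreement of the arrays was seen. In the planned fit, KO replicates 1 and 3 were not independent if KO 1.1 is a repeat of KO 3. Leaving out KO replicate 1, 2 or 3 gave 11, 9 or 264 genes, and leaving out wild-type replicate 1, 2 or 3 gave 5, 8 or 78. The 5 genes left without wild-type replicate 1 were the 5 type I keratins, so none of the other 65 genes, Ppbp, S100a7a, Il13ra1 and Stfa2 among them, kept its call there. Over 26 alternatives, that fit included, the log2 difference ran from 5.92 to 7.75 for Ppbp and 2.96 to 3.79 for S100a7a. It ran from -2.27 to -1.77 for Il13ra1 and -3.59 to -2.44 for Stfa2. Centring the arrays on ribosomal genes, which moved the median of all genes from 0.02 to 0.17, gave 60.0% higher in place of 41.4%.

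The fourth comparison concerned groups of genes fixed before the data were examined. Of 40 lists, 32 had at least 5 testable members, and besides the type I keratins 6 shifted in camera, 2 higher and 4 lower in KO. Actin and focal adhesion genes shifted higher, with 19 of 21 members positive and a mean log2 difference of 0.39 (adjusted p = 0.00246; adjusted p = 0.885 with an estimated correlation). The actin list's mean log2 level was 10.14, 10.17 and 10.02 in KO replicates 1, 2 and 3 and 9.76, 9.45 and 9.95 in wild type. Its mean difference ran from 0.26 to 0.54 over its alternatives. The actin-bundling protein Fscn1 read 2223 ± 747 in KO and 1085 ± 329 in wild type, and the calponin Cnn2 256 ± 58.8 and 149 ± 53.5 (SD, n = 3 each). Tight and adherens junction genes also shifted higher, with 15 of 17 members positive and a mean of 0.46 (adjusted p = 0.0106; adjusted p = 0.885 with an estimated correlation). The tight junction protein Cldn4 read 1356 ± 393 in KO and 595 ± 185 in wild type, and Cldn6, not above background on any wild-type array, was measured at least 7.56-fold higher (adjusted p = 0.165). No member of either list passed limma's test over all genes (5 actin and 6 junction genes had an unadjusted p under 0.05), and 0 actin and 2 junction genes passed when adjusted over the list alone. Without KO replicate 3 the junction list did not pass (adjusted p = 0.0772, against 0.00135 to 0.0772 over its alternatives).

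Regulators of spinous differentiation, the step at which keratinocytes leave the basal layer, shifted lower, with 15 of 16 members negative and a mean of -0.53 (adjusted p = 0.00112; adjusted p = 0.885 with an estimated correlation). The transcription factor Zfp750 read 608 ± 318 in KO and 1204 ± 60.9 in wild type, and Cebpb 1643 ± 433 and 3192 ± 245 (SD, n = 3 each). Cholesterol biosynthesis genes shifted lower, with 14 of 17 negative and a mean of -0.61 (adjusted p = 0.00112; adjusted p = 0.885 with an estimated correlation). Fdps, farnesyl diphosphate synthase, read 790 ± 518 in KO and 1792 ± 478 in wild type, and Lss, lanosterol synthase, 472 ± 202 and 1095 ± 406. In these lists 0 members passed limma's test over all genes (4 spinous and 9 cholesterol genes had an unadjusted p under 0.05), while 1 spinous and 0 cholesterol genes passed when adjusted over the list alone. The cholesterol list's mean log2 level was 8.57 in KO replicate 3, within the wild-type range of 8.47 to 8.79, and 7.57 and 7.85 in KO replicates 1 and 2. The spinous list's was 8.04 in KO replicate 3 and 7.36 and 7.28 in KO replicates 1 and 2, against 7.78 to 8.26 in wild type.

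Unfolded protein response genes shifted lower, with 16 of 23 negative and a mean of -0.38 (adjusted p = 0.0237; adjusted p = 0.885 with an estimated correlation). The 6 members that passed when adjusted over the list alone, all lower, were Chac1 and Trib3, named by the fixed rule, and Herpud1, Atf4, Asns and Sesn2, named after their values were seen. Atf4 encodes a stress-response transcription factor and Asns an asparagine synthetase. Chac1 read 884 ± 587 in KO and 3195 ± 1671 in wild type (SD, n = 3 each). The stress genes Ddit3, Atf3 and Ppp1r15a, also named after their values were seen, differed by -0.96, -0.16 and 0.09 and did not pass over the list alone. The endoplasmic reticulum chaperones Hspa5 and Hsp90b1, likewise named afterwards, differed by -0.06 and 0.09 on the log2 scale. No member passed limma's test over all genes (10 had an unadjusted p under 0.05). The list's mean log2 level was 8.18, 8.30 and 8.50 in KO replicates 1, 2 and 3 and 8.77, 8.93 and 8.43 in wild type, so KO replicate 3 lay above wild-type replicate 3. The list lost its call in 7 of 24 other alternatives (adjusted p 0.000969 to 0.170 over these). Among these were arrays averaged as labelled (0.0804) and the fits without KO replicate 1 (0.170) or wild-type replicate 2 (0.109).

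Oxidative phosphorylation genes shifted lower by a small amount, with 39 of 48 negative and a mean of -0.11 (adjusted p = 0.0259; adjusted p = 0.456 with an estimated correlation). Ndufa1, a complex I subunit, read 1617 ± 92.0 in KO and 2081 ± 83.7 in wild type, and Sdhc, of complex II, 721 ± 159 and 1034 ± 251 (SD, n = 3 each). No member passed limma's test over all genes and 0 passed when adjusted over the list alone. An unadjusted p under 0.05 was found for 2 of the 48, against 17.1% of all genes tested. Ribosomal centring moved all genes alike, so the list's mean read 0.04 there (camera adjusted p = 0.226). Its difference from the median of all genes was -0.13 with and without the centring. Such centring cannot change that difference, so the equal values are no evidence that the shift held. The call was lost in 6 of 24 other alternatives (adjusted p 0.00386 to 0.226 over these), among them the centring and the fits without KO replicate 3 (0.0546) or wild-type replicate 3 (0.0886).

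**Figure D3:**
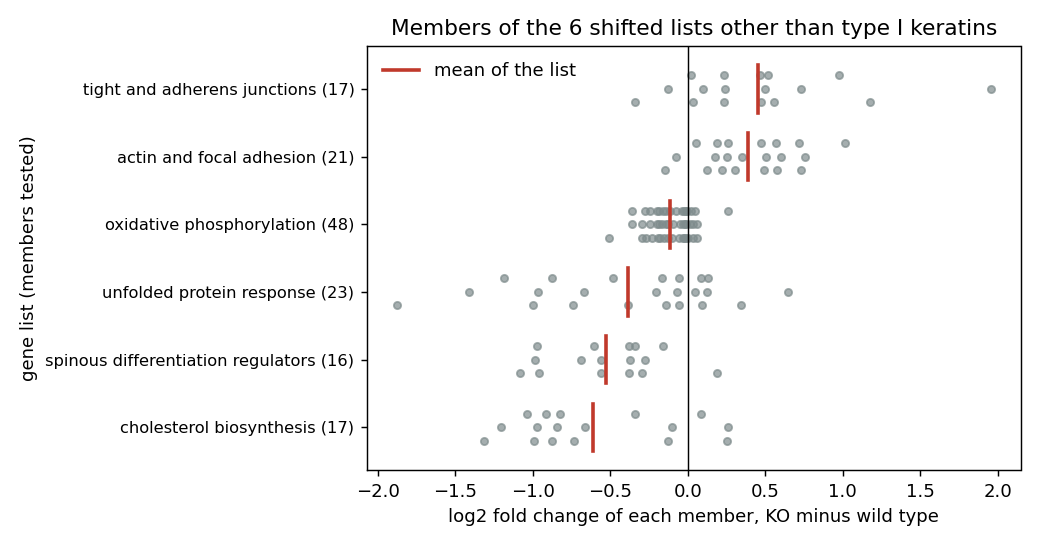
Each grey point is the log2 fold change (KO minus wild type) of 1 member of a list, and the red line is the list's mean, from -0.61 for cholesterol biosynthesis to 0.46 for tight and adherens junctions. Oxidative phosphorylation members lay close to 0 with a mean of -0.11, or 0.04 when centring on ribosomal genes moved all genes up. The difference from the median of all genes, -0.13 in both, cannot change under such centring.

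Differentiation products and inflammatory genes did not shift as lists. Of 35 cornified envelope genes, which build the outer barrier, 0 passed limma's test and 8 had an unadjusted p under 0.05, and the list did not shift (adjusted p = 0.826; mean 0.04, median -0.03). The list's mean log2 level was 8.32 in KO replicate 3 against 6.43 and 6.96 in KO replicates 1 and 2, and 6.68 to 7.48 in wild type. Without KO replicate 3 its mean was -0.50 (adjusted p = 0.00781), and that of the epidermal lipid barrier list turned from 0.08 to -0.30 (adjusted p = 0.0310). Both values used camera's preset correlation of 0.01, while the estimated correlations of these lists in the main fit were 0.57 and 0.49. Chemokines and NF-kB targets had 13 of 18 members positive and did not shift (adjusted p = 0.0938; 0.0337 to 0.277 over its alternatives). It passed as higher in 7 of 24 alternatives, among them the fits without KO replicate 1 (0.0483), wild-type replicate 2 (0.0337) or wild-type replicate 3 (0.0491). In this list 0 members passed limma's test over all genes (8 had an unadjusted p under 0.05) and 7 passed when adjusted over the list alone, 6 of them higher. Cxcl5, a neutrophil chemokine, read 1594 ± 1476 in KO and 60.8 ± 35.6 in wild type, and Cxcl3 160 ± 92.0 and 21.3 ± 22.4 (SD, n = 3 each).

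Markers of other skin cells were measured beside these groups. All 8 melanocyte markers were negative in KO, with 0 passing limma's test (0 at an unadjusted p under 0.05) and no shift of the list (adjusted p = 0.0938). The list passed as lower in 10 of 24 alternatives (adjusted p 0.0114 to 0.597) and in camera on ranks (adjusted p = 0.0466), so a lower level of these markers in KO is not excluded. All of these passes used camera's preset correlation of 0.01, whereas the list's estimated correlation was 0.84. With that estimate camera's adjusted p was 0.885, and fry gave 0.678. Among the 10 were the fits without KO replicate 1 (0.0255), KO replicate 2 (0.0380) or wild-type replicate 2 (0.0114). The planned pairing of arrays (0.0204) was another, in which KO replicate 1 was averaged with the array close to KO replicate 3. The melanocyte list's mean log2 level was 5.47 in KO replicate 3 and 7.44 in wild-type replicate 1, against 6.25 to 6.74 in the other 4 replicates. The pigment genes Pmel and Dct differed by -1.06 ± 0.77 and -0.97 ± 0.52 (SE). Of 11 fibroblast markers 0 passed limma's test and 1 had an unadjusted p under 0.05, and the list did not shift in camera (adjusted p = 0.305). The fibroblast list passed as lower without wild-type replicate 2 (0.00664, against 0.00664 to 0.984 over its alternatives). That fit used the preset correlation, while the list's estimated correlation was 0.49 in the main fit. Dcn, a dermal matrix gene, read 173 ± 159 in KO and 387 ± 378 in wild type (SD, n = 3 each). The Y-linked gene Eif2s3y was bright in KO replicates 2 and 3 and in wild-type replicate 2, so the genotypes did not hold equal numbers of male cultures. With this sex difference as a block, chosen after seeing the data, 40 genes changed.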

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

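Averaging arrays as labelled was the planned main fit and became an alternative after the arrays were seen. The settings that blocked on the matched culture, refitted normexp, floored dim values, centred on ribosomal genes, blocked on sex, left out KO 3 with WT 2 or added unnamed probes were chosen after seeing the data. The 70 genes changed became 261 with arrays averaged as labelled, 277 with the matched culture as a random block, 965 with all 8 arrays as separate replicates, 1593 with the labelled culture as a random block and 940 with array weights. The estimated block correlation was 0.83 for the matched culture and -0.33 for the labelled culture. The count of 1593 thus rests on a block that the arrays did not bear out. The count was 6 at an adjusted p under 0.01 and 40 with a sex block. Between settings that kept it within 1.5 times it ran from 57 without the 1.1 arrays to 99 without KO 3 and WT 2. Leaving out each replicate gave 5 to 264 genes, fewest without wild-type replicate 1 and most without KO replicate 3. The 7 lists shifted became 11 with no detection filter, 4 at an adjusted p under 0.01, 13 without KO 3 and WT 2, 2 with fry, 0 with an estimated correlation and 8 to 12 with each replicate left out. Fry kept type I keratins and oxidative phosphorylation. The count of 965 took each repeat array as a replicate of its own, so its p-values treat repeat measurements as independent samples. The count of 261 averaged KO 1 with an array close to KO 3. Its KO replicates 1 and 3 were thus not independent if that array is a repeat of KO 3. How much this or other causes changed the counts was not tested. Counts moved both ways when a replicate was left out, with 264 genes without KO replicate 3 and 5 without wild-type replicate 1. The mean of the epidermal lipid barrier list reversed to -0.30 without KO replicate 3 and ran up to 0.29 without KO replicate 1.

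The Tslp difference ran from 0.92 with an offset of 50 to 2.43 with values floored at the background limit, was positive under all 26 alternatives, and passed in 0 of them (adjusted p 0.0525 to 0.345). Of 806 values of the 31 named genes that passed, 626 still passed and 180 did not, with 0 reversals. Of 2020 values of the other 78 named genes, 167 passed. Of 768 values of the 32 lists, 703 stayed on their side of the threshold, 15 lost it and 49 gained it.

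With the replicate number as a block 21 genes and 8 lists passed. Correlations of same-numbered replicates' deviations were 0.06, 0.02 and -0.35, and not every sample correlated best with its own number, so the numbers were not taken as pairs. Background corrections starting from non-normalized signals and a chip block were not run, because those signals could not be given to samples and no chip is named. Tslp in wild type was dim, at 15.6 against a background limit of 6.30, and its fold moved with the offset and the floor.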

Other observations

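Among the lists not yet described, hemidesmosome and basement membrane genes had 13 of 17 members positive and did not shift (adjusted p = 0.0745), though the list passed in camera on ranks (adjusted p = 0.0481). Col4a2 and Nid1, basement membrane components, read 1063 ± 271 and 458 ± 487 in KO against 382 ± 231 and 70.8 ± 35.6 in wild type (SD, n = 3 each). Targets of YAP and SRF had 13 of 18 positive (adjusted p = 0.0776), and Ccn2, a matrix-associated growth regulator, read 3098 ± 1739 in KO and 556 ± 305 in wild type. Neither gene group had a member past limma's threshold over all genes (6 and 4 had an unadjusted p under 0.05), while 2 and 4 members passed when adjusted over the list alone. The 2 were Col4a2, higher, and Col7a1, an anchoring collagen named after its values were seen, which was lower (log2 difference -0.78). Targets of p53 had 13 of 21 negative (adjusted p = 0.113), desmosome genes 9 of 13 negative (0.149), interferon-stimulated genes 9 of 13 negative (0.249) and NRF2 antioxidant genes 16 of 26 positive (0.249). Leaving out 1 replicate brought several of these lists past the threshold in camera at its preset correlation. With an estimated correlation 0 lists passed in the main fit. Without KO replicate 3 the hemidesmosome (0.00847), YAP and SRF (0.0367) and desmosome lists (0.00790) passed, as did antimicrobial peptides (0.00847). Without wild-type replicate 3 the hemidesmosome (0.00404), desmosome (0.0236), p53 (0.0358) and interferon lists (0.0311) passed. The p53 list passed without wild-type replicate 1 (0.0410) and the NRF2 list without KO replicate 1 (0.00469). Over their alternatives the adjusted p ran from 0.00404 to 0.259 for hemidesmosome, 0.0245 to 0.194 for YAP and SRF and 0.00790 to 0.405 for desmosome genes. It ran from 0.00809 to 0.479 for p53, 0.0311 to 0.898 for interferon, 0.00469 to 0.974 for NRF2 genes and 0.00847 to 0.990 for antimicrobial peptides. Cryab, a small heat shock protein, read 456 ± 308 in KO and 62.4 ± 28.9 in wild type (adjusted p = 0.0811), and its heat shock list did not shift (adjusted p = 0.938).

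The remaining lists did not shift either. Their adjusted p values were 0.282 for basal keratinocyte identity, 0.305 for epigenetic and histone regulators, 0.314 for ribosome and translation, 0.537 for mitochondrial lipid and biogenesis genes and 0.621 for proliferation. They were 0.802 for antimicrobial peptides and for other intermediate filaments, 0.826 for glycolysis and hypoxia and for the epidermal lipid barrier, 0.843 for EGFR ligands, and 0.938 for matrix remodelling and for desquamation. Endothelial, leukocyte, Merkel cell, muscle, adipocyte, Schwann and erythroid lists had 1 to 4 bright members each and were not tested. Their brightest member on average, Mbp, read 592 ± 80.8 in KO and 356 ± 133 in wild type (SD, n = 3 each). Stmn2, a neural marker of the Schwann and neural list, read 69.6 ± 32.7 in KO and 10.9 ± 3.80 in wild type, a log2 difference of 1.61 ± 0.27 (SE). It did not pass over all genes (limma adjusted p = 0.0551; 0.00119 to 0.230 over its alternatives, with 8 of 26 past the threshold) and passed when adjusted over the list alone (0.00200). Within genotypes, the leading component of the deviations held 49.1% of the variance and set KO replicate 3 (37.7) apart from KO replicates 1 (-22.9) and 2 (-14.8). Of the 100 genes highest along it, 11 were cornified envelope genes. The agouti gene a, chosen after its values were seen, read -2.68 in wild-type replicate 1 and 2.30 on its repeat array, against 452 to 2360 on the other 6 arrays.

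Of the tests that follow, the test of other groupings was planned, and those on array 1.1, Hprt and the flanking genes were chosen after the results were seen. Regrouping the 6 replicates gave 10 splits, too few for a share under 0.05. The real grouping gave 70 genes and was the only 1 of the 10 splits to reach that number, and the highest of the others gave 2.

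KO array 1.1 could be a repeat of replicate 1, as its label says, or of replicate 3. The SD of its log2 differences was 0.640 from KO 1 and 0.213 from KO 3, and the repeat pair of wild-type arrays had 0.205. The Y-linked gene Eif2s3y read 1022 on KO array 1.1, 1065 on KO 3 and -2.27 on KO 1. Hprt, described below, read 65.9, 48.3 and 2060 on the same arrays. These values argue against a repeat of KO 1 and go with a repeat of KO 3, so a wrong number on 1 KO array is a candidate explanation. Whether array 1.1, or array 3 and array 1 together, carries the wrong number stays open.

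Hprt, a housekeeping purine salvage gene on the X chromosome, averaged 49.1 in KO replicate 3 and wild-type replicate 2 and 2863 in the other 4 replicates on its brightest probe. A sequence variant under 1 probe is argued against, because all 3 Hprt probes were lower in both replicates than in every other. A lower level in all male cultures is argued against by KO replicate 2, which held the male transcript and read 4029. Both low replicates also held that transcript, and no replicate without it was low, so a link with sex is not excluded. Loss of a longer stretch of the chromosome is argued against by the 10 nearest tested neighbours, whose median log2 difference was -0.17 against -5.44 for Hprt. An Hprt allele carried by some of the embryos, across both genotypes, may account for it and was not tested.

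A local effect of the deletion on genes beside the type I keratin cluster was looked for with 10, 20 and 40 tested genes on each side. Their median log2 differences were -0.09, -0.13 and -0.01, lower than in 87.7%, 97.6% and 69.8% of equally large windows elsewhere. Of these genes 0 passed limma's test. Among the 40 nearest, 9 had an unadjusted p under 0.05, 8 of these lower, against 17.1% of all genes tested. The answer turned with the window, so a weak effect on nearby genes could neither be shown nor excluded.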
